A study of Mus musculus with 10 samples.

How the data were processed

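Gene counts were deposited as 2 tables, one for 6 heart libraries and one for 4 macrophage libraries. Per the labels' protocols, poly(A) RNA was prepared with the NEBNext Ultra RNA kit, whose reads do not mark the strand, and the protocol text says that RNA came from livers although the samples are hearts and macrophages. Per the submitters' processing notes, reads were aligned with HISAT2 (version 2.2.1) and the authors counted reads per gene with featureCounts, whose version is not given, to make the deposited counts. The labels list both GRCm39 and mm10 as the genome build, so the build of the counts is not settled, and coordinates in the report are those of GENCODE M21 on GRCm38. All values were whole numbers, 0 columns were left without a sample, and 52081 of 55357 gene identifiers were named from GENCODE.

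Total counts were 13.5, 13.7, 14.9, 14.1, 14.8 and 14.4 M in hearts (saline 1 to 3, then IL-10 1 to 3) and 17.9, 16.7, 18.6 and 17.2 M in macrophages (wild type 1 and 2, then knockout 1 and 2). Mitochondrially encoded genes held 33.7% to 39.4% of the counts in hearts and 2.43% to 3.12% in macrophages, and mt-Co1 alone 15.8% to 17.5% in hearts. A floor of 3 counts corresponds to 0.201 to 0.222 CPM (counts per M counts, M for mega) in a heart and 0.161 to 0.179 in a macrophage library.

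Each table was analysed alone in R 4.3.3. Genes were kept by edgeR's filterByExpr (edgeR 4.0.16, minimum count 10, minimum total 15), libraries were scaled by TMM, and groups were compared with edgeR's quasi-likelihood test, IL-10 over saline in hearts and knockout over wild type in macrophages. p-values were adjusted by Benjamini-Hochberg over all tested genes, and a gene was called at an adjusted p under 0.05. CPM are on TMM-scaled library sizes. Standard errors (SE) are the absolute log2 fold change divided by the square root of the test's F. Of 49 gene lists written down before the data were examined, those with 5 or more tested members (43 in hearts, 34 in macrophages) were tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the lists. Camera with a correlation estimated per list was run beside it. Members of each list were also adjusted over the list alone. Genes called in macrophages, in each direction, were tested as sets in the hearts.

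Genes named in the report follow a rule written at the same time. Fixed genes are given whether or not they passed. The 10 largest rises and 10 largest falls are taken among called genes with a mean of at least 1 CPM and no overlap of the groups, with unnamed genes and pseudogenes passed over. These were 3 rises and 0 falls in hearts and 1 rise and 2 falls in macrophages. Up to 4 members with the smallest p are given per described list. Some genes that the rule names are not reported here. Genes chosen after their values were seen are said to be so. Fold changes against a group without counts are given as bounds, against 3 counts over the group, and those against 1 to 3 counts as ratios with a 95% counting interval.

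Alternatives were DESeq2 size factors, upper-quartile scaling, library size alone, no filter, a filter of 1 CPM in every library of a group, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom, the replicate number as a block, fry in place of camera, an added absolute log2 fold change of 1, and leaving out each library. Mitochondrial genes were left out in one more run, chosen after the data were seen. Where a library was left out of a macrophage group, the lone library was assumed to vary like the other group. The procedure was tested on simulated data with 200 genes changed. It recovered 78% of 2-fold and 97% of 4-fold changes in the heart design with 4 false calls, and 60% and 91% in the macrophage design with 5. The simulated genes took their spread from the trend over all genes, without a spread of their own, so the real data may do worse.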

Results

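Poly(A) RNA was sequenced from 6 heart libraries of Cd163-/- mice and from 4 libraries of cultured mouse peritoneal macrophages. CD163 is the macrophage scavenger receptor that takes up haptoglobin-haemoglobin complexes. The series' design text describes transverse aortic constriction, a surgical narrowing of the aorta that overloads the left ventricle, in male mice 8 weeks old. Recombinant interleukin-10 (IL-10), an anti-inflammatory cytokine, was given to Cd163-/- mice under the skin at 50 µg/kg/day on listed days from day 0 to day 27. The heart groups were saline (n = 3) and IL-10 (n = 3). The labels of the single hearts do not state the surgery, and no sham-operated or wild-type heart was analysed here. The macrophages were drawn from the peritoneal cavity after thioglycolate, an irritant that recruits them, selected by adherence and treated with 100 nM dexamethasone, a synthetic glucocorticoid, for 48 h. They were wild type (n = 2) or Cd163-/- (n = 2). Nothing states that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Total counts were 13.5, 13.7 and 14.9 M in the saline hearts, 14.1, 14.8 and 14.4 M in the IL-10 hearts, 17.9 and 16.7 M in wild-type macrophages and 18.6 and 17.2 M in knockout macrophages. Levels are given as CPM (counts per M counts of the TMM-scaled library, M for mega), mean ± SD over the libraries of a group. Coordinates are those of GRCm38 in GENCODE M21.

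Cd163 itself (ENSMUSG00000008845, chromosome 6, 124304656 to 124330527) was read first, as the targeted gene. Wild-type macrophages had 352 and 205 counts and knockout macrophages 9 and 14, or 17.0 ± 5.58 against 0.613 ± 0.233 CPM (n = 2 each). The fold change was -4.79 on the log2 scale (SE 0.39), with an adjusted p = 0.0013 by edgeR's quasi-likelihood test. The labels do not state which part of the gene was deleted, so the residual reads could not be placed inside or outside it. The Cd163-/- hearts held 45, 47 and 57 Cd163 counts after saline and 37, 43 and 34 after IL-10, or 3.46 ± 0.181 and 2.70 ± 0.404 CPM. That is above the 0.613 CPM of knockout macrophages, although the macrophage gene Adgre1 was at 35.6 and 37.3 CPM in the heart groups and at 622 CPM in those cells. The loss of Cd163 transcript seen in the macrophages is therefore not shown in the hearts, whose Cd163-/- genotype is taken from the labels, and no wild-type heart was analysed here. The difference between the heart groups (log2 -0.36, SE 0.26) did not pass the test (edgeR quasi-likelihood, adjusted p = 0.395). Il10 was at 0 to 2 counts in every heart, below the test's count filter.

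The first comparison asked what IL-10 changed in the hearts given as Cd163-/- in the labels. In IL-10 hearts 30 of 35 cell cycle genes, 32 of 41 extracellular matrix genes and 9 of 19 cardiac stress genes fell. As lists these were called by camera, but not with an estimated correlation (adjusted p = 0.285, 0.638 and 0.638). Ccnb1, the mitotic cyclin B1, was at 0.402 ± 0.0458 CPM against 7.95 ± 1.75 after saline, Postn, a matrix protein of activated fibroblasts, at 358.3 ± 71.4 against 973 ± 120.3, and Nppa, the atrial natriuretic peptide, at 398 ± 149 against 1297 ± 379.6 (n = 3 each). Of the interferon-response genes 24 of 35 fell and of the red blood cell genes 6 of 6, while 15 of 44 nuclear genes of mitochondrial respiration, 13 of 29 of fatty acid oxidation and 7 of 21 of cardiac ion channels rose. With an estimated correlation none of these 5 lists was called (adjusted p = 0.603 and 0.638, then 0.939, 0.638 and 0.638). Of 13718 genes tested, 941 rose and 919 fell in IL-10 relative to saline hearts (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 3877 had an unadjusted p under 0.05. The groups did not overlap in 31.6% of tested genes, where chance gives 10%.

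Cell division was the group with the strongest test. Of 35 tested cell cycle genes, 30 fell and 0 rose, and 31 fell when adjusted over the list alone. Their median log2 fold change was -2.09 (limma camera, adjusted p = 2.56e-28; adjusted p = 0.285 with an estimated correlation). Mki67, the proliferation marker Ki-67, fell from 10.6 ± 1.62 to 1.60 ± 0.328 CPM, Top2a, the topoisomerase of dividing cells, from 19.0 ± 2.71 to 3.77 ± 0.457 CPM, and Ccnb1 had a log2 fold change of -4.28 (SE 0.32; edgeR quasi-likelihood, adjusted p = 1.55e-06). Of the 10 largest falls of any named gene, 8 were, by a grouping made after they were seen, genes of the dividing cell. Beside Ccnb1 these were the spindle and kinetochore genes Aspm (log2 -4.25), Bub1 (-3.48) and Ndc80 (-3.46), the mitotic kinase gene Pbk (-3.61), Pimreg (-3.63), Depdc1a (-3.44) and Iqgap3 (-3.29). Mki67 was at 1.25 to 12.1 CPM across the 6 hearts, so these transcripts were a small part of the RNA.

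The 2 other genes among the largest falls were Sprr1a and Tnnt3. Sprr1a, a stress-induced gene of cardiomyocytes, fell from 52.2 ± 42.4 to 1.69 ± 0.782 CPM (log2 -4.95, SE 0.55; edgeR quasi-likelihood, adjusted p = 3.90e-05), or -4.09 without saline replicate 3. Tnnt3, the fast skeletal troponin T, had a log2 fold change of -3.37 (SE 0.70) that was -2.53 without saline replicate 3 and -4.81 without IL-10 replicate 1. In the list of cardiac stress genes, 9 of 19 tested genes fell and 0 rose, and 11 fell when adjusted over the list alone (median log2 -0.521; camera adjusted p = 7.42e-05; adjusted p = 0.638 with an estimated correlation). Nmrk2, a nicotinamide riboside kinase of stressed muscle, fell from 109 ± 24.9 to 14.4 ± 1.20 CPM (log2 -2.92, SE 0.16; edgeR quasi-likelihood, adjusted p = 3.63e-08). Fhl1, a LIM-domain protein of the sarcomere, fell by 1.51 and Nppa (chromosome 4, 148000722 to 148002079) by 1.70 (SE 0.24) on the log2 scale. The stress markers Nppb (log2 -0.40), Myh7 (-0.43) and Acta1 (0.25) and the adult myosin gene Myh6 (0.06) did not pass the test, with adjusted p from 0.0963 to 0.833 (edgeR quasi-likelihood). Myh7 passed without saline replicate 1 (log2 -0.59), and Nppb passed in DESeq2.

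The extracellular matrix genes moved the same way. Of 41 tested members, 32 fell and 1 rose, and 33 fell and 1 rose when adjusted over the list alone (median log2 -0.824; camera adjusted p = 3.50e-13; adjusted p = 0.638 with an estimated correlation). Postn (chromosome 3, 54361109 to 54391037) fell by 1.44 (SE 0.15) on the log2 scale, Thbs4, a thrombospondin of stressed myocardium, by 1.46, Fn1, fibronectin, by 1.77, and the fibrillar collagen genes Col1a1 and Col3a1 by 1.34 and 1.02. Col1a1 was at 242 ± 96.1 CPM after saline and 95.6 ± 20.6 after IL-10. The fibroblast marker list, which shares Col1a1, Dcn and Lum with the matrix genes, went both ways. Of its 15 tested genes 5 rose and 5 fell, or 6 and 5 when adjusted over the list alone, and the list was not called (median log2 0.177, mean -0.0559; camera adjusted p = 0.845). Gsn, the actin-severing protein gelsolin, was among its rises (log2 0.90). Without saline replicate 3 the counts were 2 and 2.

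**Figure D1:**
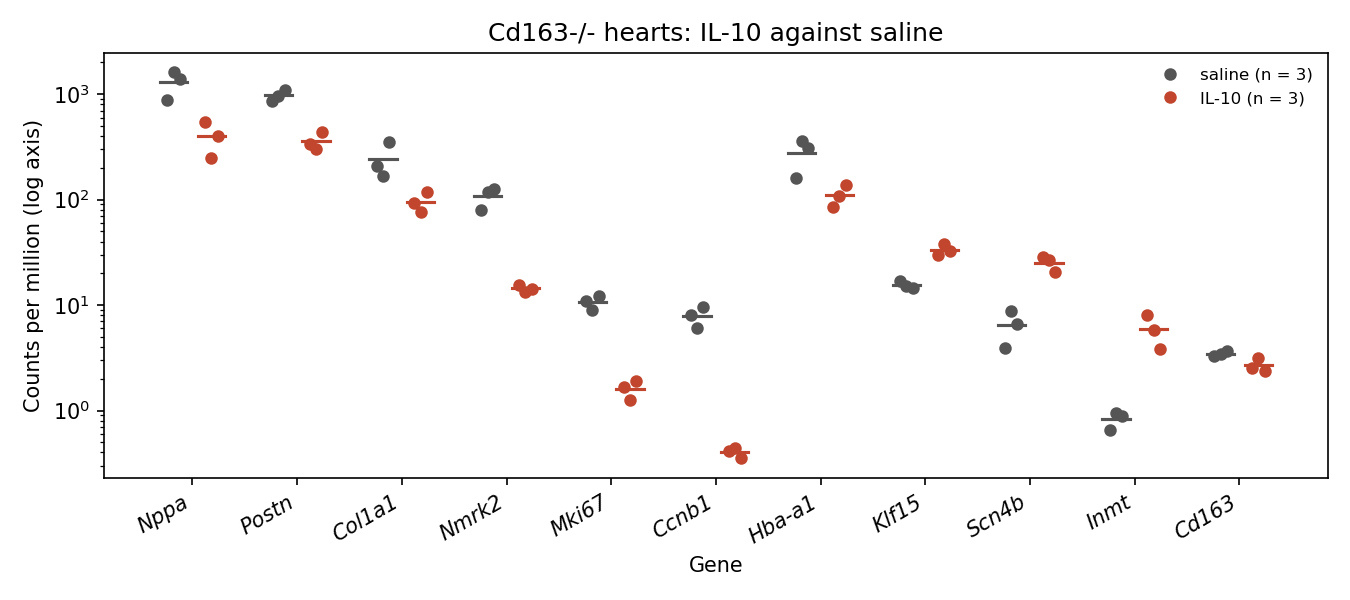
Level of 11 genes in the 6 Cd163-/- hearts, in CPM on a log axis; each point is a library, each bar the mean of 3, grey for saline and red for IL-10. The groups are apart for all 11 genes, from Ccnb1 (7.95 against 0.402) to Cd163 (3.46 against 2.70), and Cd163 alone of them did not pass the test.

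Interferon-stimulated genes fell in part after IL-10. Of 35 tested genes 24 fell and 0 rose, 28 fell when adjusted over the list alone, and the median log2 fold change was -0.668 (camera adjusted p = 5.59e-15; adjusted p = 0.603 with an estimated correlation). Without IL-10 replicate 2 the count was 15. The antiviral genes Mx1 (log2 -2.31), Ifit3 (-1.22) and Oasl2 (-1.19) were among the falls, and reads of Ifit3 can be shared with its near-identical neighbour Ifit3b. Cxcl10, an interferon-induced chemokine, fell from 8.36 ± 1.45 to 1.37 ± 0.459 CPM. Of the other inflammatory chemokines, Cxcl5 (log2 1.80) and Cxcl1 (1.12) rose, with means under 5 CPM and overlapping groups. The Cxcl1 call was lost without any 1 of the 6 hearts except IL-10 replicate 1, at adjusted p from 0.053 to 0.234 (edgeR quasi-likelihood), and in limma-voom (0.0867). The Cxcl5 call was lost without saline replicate 3, IL-10 replicate 2 or IL-10 replicate 3 and in DESeq2, at adjusted p from 0.0648 to 0.0845. The proinflammatory list of 17 tested genes was not called (2 rose and 1 fell, or 2 and 2 when adjusted over the list alone). Its members Il1b (log2 -0.03) and Il6 (1.24) did not pass the test (edgeR quasi-likelihood, adjusted p = 0.976 and 0.126), and Il6 passed without IL-10 replicate 1 (log2 1.64, adjusted p = 0.0351) and was at 0.36 without IL-10 replicate 3. The list was called, as lower, without IL-10 replicate 3 (median log2 -0.42; camera adjusted p = 0.0301).

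Macrophage transcripts did not move as 1 group. Adgre1, which encodes the macrophage antigen F4/80, was at 35.6 ± 10.5 CPM after saline and 37.3 ± 3.17 after IL-10 (log2 0.06; edgeR quasi-likelihood, adjusted p = 0.835). Of 23 tested macrophage markers 3 fell, among them Cx3cr1, the fractalkine receptor (log2 -1.01), and 0 rose, in the whole table and when adjusted over the list alone. With 1 heart left out 1 to 7 fell, 7 of them without saline replicate 2 and 1 without saline replicate 1 or 3 or IL-10 replicate 1 or 2. The list was not called (camera adjusted p = 0.669; median log2 0.0227, mean -0.145). Without saline replicate 2 it was called as lower (median log2 -0.236; camera adjusted p = 0.0105). The median is below 0 also without IL-10 replicate 2 or 3, and when libraries are scaled by upper quartile (-0.0237) or by size alone (-0.0455). Among 16 markers of resident cardiac macrophages, 5 rose and 2 fell (the same when adjusted over the list alone; not called, camera adjusted p = 0.555). The rises included the phosphatidylserine receptor Timd4 (log2 1.51), the hyaluronan receptor Lyve1 (0.73) and Cbr2 (0.50). Without saline replicate 1 or 2 the list's median turned from 0.107 to -0.015 or -0.031, and without saline replicate 3, IL-10 replicate 1 or IL-10 replicate 2 none of its genes fell. Among 13 markers of monocytes and recruited macrophages 5 fell and 0 rose, 6 fell when adjusted over the list alone, and the list was not called (median log2 -0.819; camera adjusted p = 0.137) except without saline replicate 2 (adjusted p = 0.00318). Its fall with the smallest p was that of fibronectin, Fn1 (log2 -1.77), and the list shares Fn1 and Thbs1 with the matrix genes. Osteopontin, Spp1 (log2 -2.21), the chemokine receptor gene Ccr2 (-1.35) and Cd44 (-0.92) fell too. The groups overlapped for Spp1 and Ccr2. Spp1, Ccr2 and Cd44 were not called by DESeq2.

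The IL-10 receptor gene Il10ra was at 8.95 ± 3.73 CPM after saline and 7.98 ± 1.97 after IL-10. Socs3, the feedback inhibitor induced by IL-10 through STAT3, was at 13.9 ± 5.59 and 26.5 ± 15.9 CPM (log2 0.93, SE 0.33). Neither passed the test (edgeR quasi-likelihood, adjusted p = 0.70 and 0.0757), and Socs3 did without saline replicate 1 (adjusted p = 0.0354) or IL-10 replicate 1 (adjusted p = 0.0055). The list of IL-10 and STAT3 response genes was not called (3 of 21 rose and 1 fell, or 5 and 2 when adjusted over the list alone; camera adjusted p = 0.137), except without IL-10 replicate 1 (adjusted p = 0.0144).

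Some genes of energy metabolism rose. Of 44 nuclear genes of oxidative phosphorylation 15 rose and 0 fell, and 26 rose when adjusted over the list alone (median log2 0.352; camera adjusted p = 4.88e-10; adjusted p = 0.939 with an estimated correlation). With 1 heart left out the count went from 4, without IL-10 replicate 2, to 26. Cox6c, a cytochrome oxidase subunit, rose by 0.61 and Uqcrfs1, the iron-sulfur subunit of complex III, by 0.64 on the log2 scale. Of 29 fatty acid oxidation genes 13 rose and 0 fell, and 17 rose when adjusted over the list alone (median log2 0.43; camera adjusted p = 3.30e-08; adjusted p = 0.638 with an estimated correlation). With 1 heart left out this count went from 7, without saline replicate 3, to 18. The beta-oxidation enzymes Eci1, Acads and Hadh rose by 0.83, 0.75 and 0.69. Of 13 respiration genes encoded in mitochondria 0 rose and 0 fell, also when adjusted over the list alone (median log2 0.0864; camera adjusted p = 0.555). That list was called as higher without IL-10 replicate 1 (median 0.215, adjusted p = 0.0343), and its median was -0.0184 without IL-10 replicate 2. Of 21 glycolysis genes 2 rose and 4 fell, or 2 and 7 when adjusted over the list alone (median log2 -0.248; camera adjusted p = 0.0604), and this list was called as lower without saline replicate 1 (adjusted p = 0.00713) or IL-10 replicate 2 (adjusted p = 0.0341). Of 21 cardiac ion channel genes 7 rose and 0 fell, and 8 rose when adjusted over the list alone (median log2 0.328; camera adjusted p = 0.00109; adjusted p = 0.638 with an estimated correlation). Scn4b, a sodium channel beta subunit, rose from 6.46 ± 2.44 to 25.2 ± 4.05 CPM, and the potassium channel genes Kcna5 and Kcnj11 rose by 0.79 and 0.69 on the log2 scale.

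Some glucocorticoid-induced genes rose. Of 21 tested genes 7 rose and 1 fell, or 10 and 1 when adjusted over the list alone (median log2 0.489; camera adjusted p = 0.00201; adjusted p = 0.589 with an estimated correlation). The transcription factor genes Klf15 (log2 1.10) and Klf9 (0.77) and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper GILZ (1.25), were among the rises. Of 24 immediate early genes 7 rose and 1 fell, or 9 and 3 when adjusted over the list alone (median log2 0.192; camera adjusted p = 0.0421; adjusted p = 0.939 with an estimated correlation). Without saline replicate 1 only 2 rose, and the list call was lost without saline replicate 1 or 2 or without IL-10 replicate 1 or 3 (adjusted p from 0.0649 to 0.436). Of 10 genes of antigen presentation on MHC class II 3 rose and 0 fell, and 4 rose when adjusted over the list alone (median log2 0.294; camera adjusted p = 0.0379; adjusted p = 0.939 with an estimated correlation). This list was not called without saline replicate 2 (adjusted p = 0.461), IL-10 replicate 1 (0.0545) or IL-10 replicate 3 (0.115). H2-Aa, a class II chain, rose by 1.07 and Cd74, the invariant chain, by 0.83 on the log2 scale in edgeR, and neither was called by DESeq2. Of 40 cytosolic ribosome genes 1 fell, Rpl3 (log2 -0.66), also when adjusted over the list alone. The list's median log2 fold change was -0.138 (camera adjusted p = 0.0421; adjusted p = 0.969 with an estimated correlation), and its call was lost without saline replicate 3 (adjusted p = 0.442), IL-10 replicate 1 (0.172) or IL-10 replicate 3 (0.427).

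Haemoglobin transcripts were lower. All 6 tested red blood cell genes fell, also when adjusted over the list alone (median log2 -1.36; camera adjusted p = 0.000301; adjusted p = 0.638 with an estimated correlation). Hba-a1, an alpha globin gene, was at 275 ± 102 CPM after saline and 110.1 ± 26.4 after IL-10. Alas2, the erythroid enzyme that starts haem synthesis, fell by 1.57, Hba-a2 by 1.68 and the beta globin gene Hbb-bt by 1.16 on the log2 scale. Hba-a1 and Hba-a2, and likewise the beta globin genes, are near-identical copies between which reads can be divided, so the single values are less certain than their sum. Liver markers were read because the RNA protocol in the labels names livers. Of 5 tested, 1 rose (Ttr, transthyretin, log2 2.51, at under 1 CPM in both groups), also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.137).

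The 10 largest rises were of mixed function. Inmt, an indolethylamine methyltransferase, rose from 0.835 ± 0.154 to 5.87 ± 2.11 CPM (log2 2.80, SE 0.34; edgeR quasi-likelihood, adjusted p = 8.49e-05). Angptl7, an angiopoietin-like secreted protein, rose by 2.64, Cyp26b1, which degrades retinoic acid, by 2.46, Gsta3, a glutathione transferase, by 2.01, Scn4b by 1.96, Rasl10a by 1.80, Irs2, an insulin receptor substrate, by 1.69, the carboxylesterase gene Ces1d by 1.63, the mitochondrial isoleucine tRNA mt-Ti by 1.61 and the phosphatase inhibitor gene Ppp1r1a by 1.56. Gsta3 and Ces1d belong to families of close copies, and mt-Ti overlaps a tRNA gene on the opposite strand, which reads of this kit do not tell apart. The Rasl10a call was lost without IL-10 replicate 1 (adjusted p = 0.0532), and that of Ppp1r1a without saline replicate 1 (0.135) or 3 (0.0587) or IL-10 replicate 2 (0.136) or 3 (0.112), all by edgeR quasi-likelihood, and in limma-voom (0.0655). Mitochondrial ribosomal RNAs, looked at after their values were seen, rose too, mt-Rnr1 by 1.31 and mt-Rnr2 by 1.42, while the nuclear long non-coding RNAs Malat1 and Meg3, chosen in the same way, fell by 1.39 and 1.89.

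The count of changed genes was 897 without IL-10 replicate 2, 1012 without saline replicate 1 and 1147 without saline replicate 3, and the share of rises among the calls was 50.6%, against 39.0% with upper-quartile scaling and 35.6% with library size alone. All 12 list calls rest on camera's preset correlation (fry keeps only the cell cycle and interferon lists), and with it the 9 other divisions of the 6 hearts into groups of 3 called up to 15 lists while calling 0 genes. The labels name no batch of the hearts. A lower share of nuclear RNA in the IL-10 libraries, left open below, could not be told apart from an effect of IL-10.

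**Figure D2:**
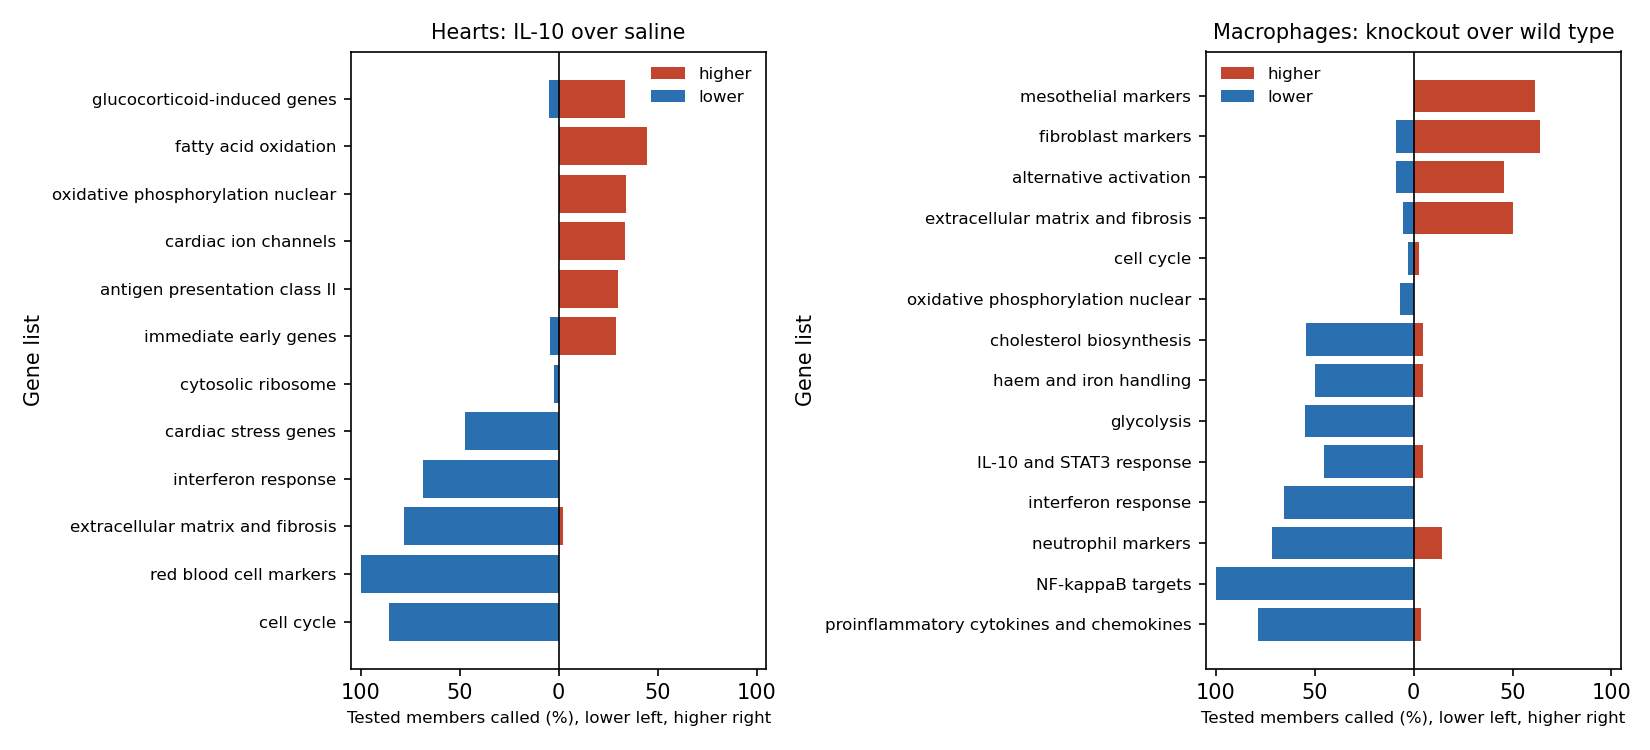
Percent of the tested members of each called gene list that passed the test, fallen to the left in blue and risen to the right in red; left panel, the 12 lists called in hearts (IL-10 over saline), right panel, the 14 called in macrophages (knockout over wild type). In hearts all 6 red blood cell genes and 30 of 35 cell cycle genes fell, and in macrophages all 20 NF-kappaB targets fell.

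The second comparison asked how macrophages without CD163 differ from wild-type cells under dexamethasone. Inflammatory transcripts were far lower in knockout cells. Il1b, which encodes interleukin-1 beta (chromosome 2, 129364570 to 129371139), was at 624 ± 329 CPM in wild-type and 0.36 ± 0.195 in knockout cells, and Tnf, tumour necrosis factor, at 2163 ± 409 and 10.9 ± 2.95 (n = 2 each). Il10 itself was lower, with 198 and 984 counts in wild-type and 23 and 35 in knockout cells. In knockout cultures 18 of 36 matrix, 8 of 13 mesothelial and 5 of 11 alternative activation genes rose. These lists were not called with an estimated correlation (adjusted p = 0.88 each), and without knockout replicate 1 the rises were 9, 0 and 2. Of 13861 genes tested, 1817 rose and 1846 fell in knockout relative to wild-type cells (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 5711 had an unadjusted p under 0.05. The groups did not overlap in 69.4% of tested genes, where chance gives 33.3%.

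Of 28 tested proinflammatory cytokine and chemokine genes 22 fell and 1 rose in knockout cells, or 26 and 1 when adjusted over the list alone. The median log2 fold change was -7.14, or -5.29 with the 3 genes that had no count in knockout cells set at their bound (camera adjusted p = 4.25e-15; adjusted p = 0.739 with an estimated correlation). Leaving out 1 library gave medians from -7.44 to -5.39. All 20 NF-kappaB target genes fell, also when adjusted over the list alone (median log2 -2.63; camera adjusted p = 5.21e-15; adjusted p = 0.739 with an estimated correlation). The largest fall of a called gene was that of Il1b (log2 -10.70, SE 0.62; edgeR quasi-likelihood, adjusted p = 0.0006), and other large falls were those of Il12b, the p40 chain of interleukin-12 (log2 -10.08), Acod1, which makes itaconate (-8.79), and Tnf (-7.64). The chemokine genes Cxcl5 (-8.32), Cxcl2 (-7.81), Cxcl1 (-7.26) and Ccl2 (-3.56), the neutrophil growth factor gene Csf3 (-8.48), the niacin receptor gene Hcar2 (-7.65) and the inflammasome sensor gene Nlrp3 (-3.18) fell too. Il12a and Csf2 had no count in knockout cells and were at least 37.8-fold and at least 32.0-fold lower, against a floor of 3 counts over the group. The ratio for Cxcl3, with 1 count in knockout cells, was 471 (95% counting interval 84.1 to 18700). The intervals and floors cover counting error only. Traf1 (log2 -4.53), the NF-kappaB inhibitor gene Nfkbia (-3.37), the adhesion molecule gene Icam1 (-3.78), the deubiquitinase gene Tnfaip3 (-3.95) and Il6 (-5.35) fell. Nos2, the inducible nitric oxide synthase, chosen after its values were seen, was at 54.0 ± 74.6 CPM in wild-type cells, with 1701 counts over both libraries against 0 in knockout cells, and did not pass the test (edgeR quasi-likelihood, adjusted p = 0.0651), which it did in DESeq2 (adjusted p = 0.0119) and without wild-type replicate 1 (5.77e-07) or 2 (0.00965). Over all its alternatives the adjusted p went from 5.77e-07 to 0.281, the highest in limma-voom. The Nos2 reads lay mostly in wild-type replicate 2, without which its log2 value was -7.52 in place of -12.9. Without wild-type replicate 2 the log2 values of Il1b, Il6, Csf3 and Cxcl5 were -10.04, -4.60, -7.66 and -7.23. Without wild-type replicate 1 that of Cxcl5 was -8.94. Without knockout replicate 1 those of Il1b, Il12b, Acod1 and Csf3 were -11.41, -9.49, -8.16 and -9.16, and without knockout replicate 2 those of Il12b, Acod1 and Cxcl2 were -10.95, -9.88 and -8.66. The Csf2 call was lost without knockout replicate 1 (adjusted p = 0.0567).

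Interferon-response genes fell in part as well. Of 35 tested 23 fell and 0 rose, and 30 fell when adjusted over the list alone (median log2 -1.98; camera adjusted p = 8.67e-09; adjusted p = 0.88 with an estimated correlation). Without knockout replicate 2 the count was 5. The list's median went from -2.8 to -1.06 with 1 library left out. The guanylate-binding protein genes Gbp5 (log2 -6.80) and Gbp2 (-4.96) and the RNA sensor gene Ifih1 (-1.73) fell. Without wild-type replicate 2 Gbp5 and Gbp2 were at -5.72 and -3.99, and without replicate 1 Gbp5 was at -7.42. The Gbp2 call was lost without knockout replicate 1 (adjusted p = 0.0506). Of 22 IL-10 and STAT3 response genes 10 fell and 1 rose, or 12 and 1 when adjusted over the list alone (median log2 -0.762; camera adjusted p = 0.00613; adjusted p = 0.88 with an estimated correlation), and 4 fell without knockout replicate 1. Tnip3 (log2 -5.47), Socs3 (-4.64), the kinase gene Pim1 (-1.91) and Junb (-1.56) fell, with Tnip3 at -6.07 without knockout replicate 2 and Socs3 at -3.71 without wild-type replicate 2. Il10 had a log2 fold change of -4.59 (SE 0.87; edgeR quasi-likelihood, adjusted p = 0.0155). It was -2.94 without wild-type replicate 2 and -5.35 without replicate 1, and the call was lost without knockout replicate 1 (adjusted p = 0.129) or 2 (adjusted p = 0.0875) and in limma-voom (adjusted p = 0.0804). Socs3 was not called without knockout replicate 1 (adjusted p = 0.0557). Il10ra was at 102 ± 23.4 and 91.5 ± 20.5 CPM (log2 -0.16) and did not pass the test (edgeR quasi-likelihood, adjusted p = 0.615).

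**Figure D3:**
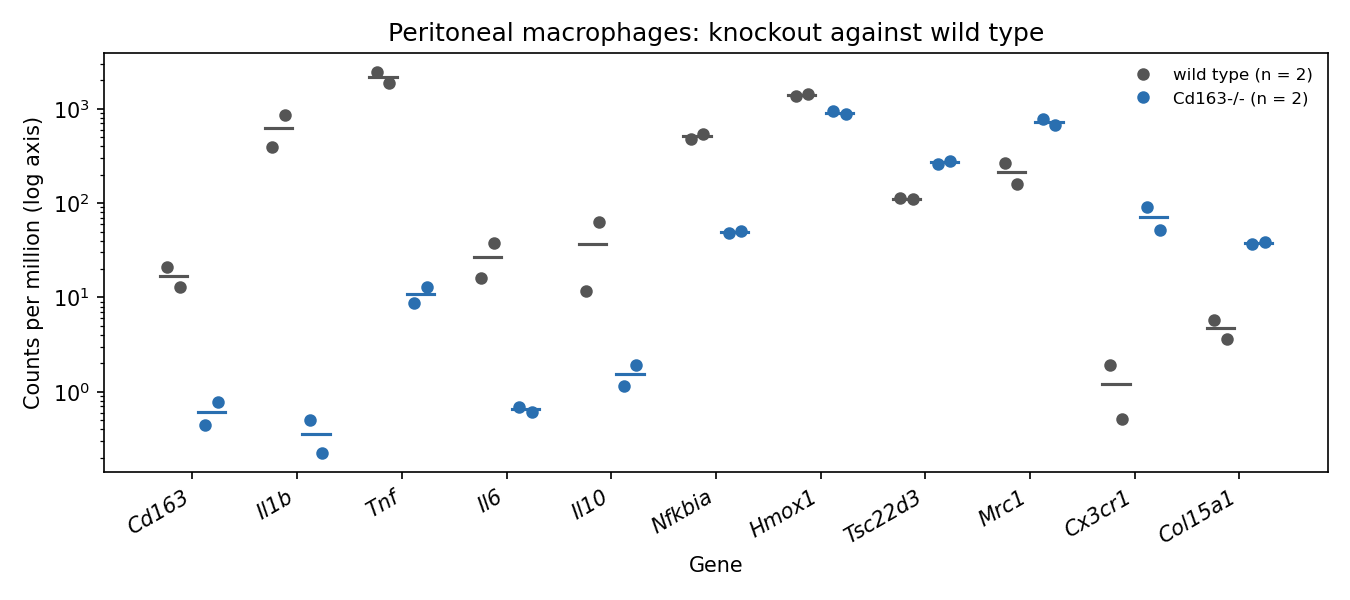
Level of 11 genes in the 4 peritoneal macrophage libraries, in CPM on a log axis; each point is a library, each bar the mean of 2, grey for wild type and blue for Cd163-/-. Il1b (624 against 0.36) and Tnf (2163 against 10.9) are lower in knockout cells, and Mrc1 (213 against 724) and Col15a1 (4.69 against 37.8) are higher.

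Glucocorticoid-induced genes, read because all cultures received dexamethasone, went both ways. Of 22 tested 6 rose and 6 fell, or 7 and 8 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.892; median log2 0.141, mean -0.243). Tsc22d3 rose from 111 ± 1.47 to 270.2 ± 11.5 CPM and Fkbp5, a co-chaperone of the glucocorticoid receptor, from 120.4 ± 25.5 to 330.1 ± 30.6 CPM. The formyl peptide receptor genes Fpr1 (log2 -3.61) and Fpr2 (-5.52), which are related in sequence, and Nr3c1, the glucocorticoid receptor gene (-1.33), fell. The list counts Nr3c1 although it encodes the receptor itself, so its fall does not tell of weaker induction. The list's rises and falls were 3 and 2 without knockout replicate 1. The calls of Fkbp5 and Nr3c1 were lost without knockout replicate 1 (edgeR quasi-likelihood, adjusted p = 0.0547 for each).

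Some alternative activation genes rose in knockout cells. Of 11 tested 5 rose and 1 fell, or 6 and 1 when adjusted over the list alone (median log2 1.09; camera adjusted p = 0.0414; adjusted p = 0.88 with an estimated correlation). Without knockout replicate 1 only 2 rose, and the list call was lost without wild-type replicate 2 (adjusted p = 0.0661) or knockout replicate 2 (adjusted p = 0.0977). The mannose receptor gene Mrc1 rose by 1.76, arginase, Arg1, by 1.09 and the lectin gene Clec10a by 3.44, or 2.77 without wild-type replicate 2 and 4.79 without replicate 1, while the transglutaminase gene Tgm2 fell by 0.79. The calls of Mrc1 and Tgm2 were lost without knockout replicate 1 (adjusted p = 0.0733 and 0.158) and those of Clec10a and Tgm2 without knockout replicate 2 (adjusted p = 0.0703 and 0.0584). Adgre1 fell from 1086 ± 189 to 622 ± 32.8 CPM (edgeR quasi-likelihood, adjusted p = 0.0273), a call that was lost without either knockout replicate (adjusted p = 0.16 and 0.167).

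Some transcripts of stromal cells rose in knockout cultures. Of 36 extracellular matrix genes 18 rose and 2 fell, or 21 and 2 when adjusted over the list alone (median log2 1.01; camera adjusted p = 1.63e-05; adjusted p = 0.88 with an estimated correlation). The collagen genes Col15a1, Col14a1 and Col6a1 rose by 3.00, 3.00 and 1.32, and Postn by 2.02. Of 13 markers of mesothelium, the lining of the peritoneal cavity, 8 rose and 0 fell, and 10 rose when adjusted over the list alone (median log2 1.62; camera adjusted p = 0.000537; adjusted p = 0.88 with an estimated correlation). Upk1b, an uroplakin of mesothelial cells, was at 22.5 ± 11.9 CPM in wild-type and 96.6 ± 23.1 in knockout cells, and the transcription factor gene Wt1, Lrrn4 and the keratin gene Krt18 rose by 0.81, 2.47 and 2.16. The mesothelial list's median went from 1.12 to 2.41 with 1 library left out. Without wild-type replicate 1 Lrrn4 and Upk1b were at 3.27 and 2.78. Of 11 fibroblast markers 7 rose and 1 fell, or 8 and 1 when adjusted over the list alone (median log2 1.50; camera adjusted p = 0.00813; adjusted p = 0.88 with an estimated correlation). The matrix proteoglycan gene Lum, which is in the matrix list too, rose by 2.29, and Pdgfra, a growth factor receptor gene of fibroblasts, fell by 1.32. Without knockout replicate 1, 9 matrix, 0 mesothelial and 1 fibroblast gene rose. The calls of Wt1, Lrrn4, Upk1b, Krt18 and Pdgfra were lost without that library (adjusted p from 0.0598 to 0.11), and those of Wt1 and Pdgfra also without knockout replicate 2 (adjusted p = 0.051 and 0.0735).

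Some genes of cholesterol synthesis, glycolysis and iron handling fell. Of 22 cholesterol biosynthesis genes 12 fell and 1 rose, or 14 and 1 when adjusted over the list alone (median log2 -0.527; camera adjusted p = 5.48e-05; adjusted p = 0.739 with an estimated correlation). Mvd, the mevalonate decarboxylase, fell by 0.92 on the log2 scale. Of 20 glycolysis genes 11 fell and 0 rose, or 13 and 1 when adjusted over the list alone (median log2 -0.613; camera adjusted p = 0.00238; adjusted p = 0.88 with an estimated correlation), among them the lactate exporter Slc16a3 (log2 -1.74), the phosphofructokinase Pfkl (-1.17) and the glucose transporter Slc2a1 (-1.20). Of 44 nuclear genes of oxidative phosphorylation 3 fell and 0 rose, 1 when adjusted over the list alone (median log2 -0.164; camera adjusted p = 0.00929; adjusted p = 0.88 with an estimated correlation). Their median turned to 0.0128 with library size alone, none fell without knockout replicate 1, and cytochrome c, Cycs, fell by 1.10. Of 22 genes of haem and iron handling, the substrates that CD163 brings in, 11 fell and 1 rose, or 11 and 2 when adjusted over the list alone (median log2 -0.54; camera adjusted p = 0.00589; adjusted p = 0.88 with an estimated correlation). The iron transporter gene Slc11a2 fell by 1.96, the thioredoxin reductase gene Txnrd1 by 1.73 and haptoglobin, Hp, fell too (log2 -5.26). Hmox1, which breaks down haem, fell from 1363 and 1438 CPM in the wild-type libraries to 938 and 889.5 in the knockout libraries (log2 -0.62; edgeR quasi-likelihood, adjusted p = 0.041), and the iron exporter gene Slc40a1 rose. Without knockout replicate 1, 1 cholesterol, 3 glycolysis and 2 haem and iron genes fell, and the calls of Cycs, Txnrd1, Hp and Hmox1 were lost (adjusted p from 0.0704 to 0.219). Those of Txnrd1 and Hmox1 were lost without knockout replicate 2 too (adjusted p = 0.058 and 0.225), and the oxidative phosphorylation list was not called (adjusted p = 0.165). Fatty acid oxidation went both ways. Of 25 genes 5 rose and 4 fell, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.433; median log2 0.221, mean -0.0702), with 0 rises without either knockout replicate. Hp was at -3.92 without wild-type replicate 2 and -5.94 without replicate 1.

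Neutrophil markers and cell cycle genes were the other called lists. Of 7 neutrophil markers 5 fell and 1 rose, or 6 and 1 when adjusted over the list alone (median log2 -2.58; camera adjusted p = 0.0195; adjusted p = 0.88 with an estimated correlation). The list's median went from -2.6 to -1.47 with 1 library left out. The protease gene Mmp9 fell by 3.11 and Mmp8 rose by 1.32. Mmp9 was at -3.87 without knockout replicate 2. Lcn2, the lipocalin that binds bacterial siderophores, had a log2 fold change of -7.53, or -5.09 without wild-type replicate 2 and -8.39 without replicate 1, and was not called without knockout replicate 1 (adjusted p = 0.106) or 2 (adjusted p = 0.0825) or in limma-voom (adjusted p = 0.067). The alarmin gene S100a8, chosen after its values were seen, fell by 2.58, or by 1.80 without wild-type replicate 2, and was not called without either knockout replicate (adjusted p = 0.0945 and 0.087). S100a9 was at 0 and 0 counts in wild-type cells. The list was not called with a stricter count filter (adjusted p = 0.0953), its median turned to 0.855 with no filter (15 genes), and 1 gene fell without knockout replicate 1. Of 35 cell cycle genes 1 rose and 1 fell, or 0 and 1 when adjusted over the list alone, while the list's median was 0.592 (camera adjusted p = 0.00813; adjusted p = 0.88 with an estimated correlation). The replication helicase gene Mcm6 rose by 0.60 and Mki67 fell by 1.41, against the direction of the list, and the list call was lost without wild-type replicate 1 (adjusted p = 0.191) or knockout replicate 1 (adjusted p = 0.281). Without wild-type replicate 2, 9 of its genes rose. The Mcm6 call was lost without wild-type replicate 1 or either knockout replicate (adjusted p from 0.0556 to 0.206).

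The largest rises in knockout cells started from low levels. Cx3cr1 rose from 1.21 ± 0.985 to 71.3 ± 27.0 CPM (log2 5.86, SE 0.52; edgeR quasi-likelihood, adjusted p = 0.00175), or by 5.22 without wild-type replicate 2 and 7.11 without replicate 1. Angptl7, which also rose in IL-10 hearts, rose by 5.55, the organic anion transporter gene Slco2b1 by 4.85, the monooxygenase gene Fmo2 by 4.50 and Slc40a1, ferroportin, by 4.33. Without wild-type replicate 1 Slco2b1 and Slc40a1 were at 5.51 and 6.18, without replicate 2 Slc40a1 was at 3.56, and Slc40a1 was not called without knockout replicate 1 (adjusted p = 0.065). Chp2, a calcineurin-like protein gene with no count in wild-type cells, was at least 30.2-fold higher against the floor of 3 counts over the group. Genes with 3 counts in wild-type cells had ratios of 43.9 (95% counting interval 14.7 to 215) for the chemokine receptor gene Cxcr3, 42.5 (14.3 to 208) for the lysophospholipid receptor gene Gpr34 and 23.1 (7.63 to 114) for the T cell receptor segment Trav13-4-dv7. The last was not called without knockout replicate 1 (adjusted p = 0.094) or 2 (adjusted p = 0.055).

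Without knockout replicate 1 the count of changed genes was 734 and without knockout replicate 2 it was 1305, while rises made up 49.6% of the calls, against 62.2% with upper-quartile scaling and 68.6% with library size alone, under which the median log2 fold change of all genes is 0.125 and 0.188, against 0.0124 with TMM. Nothing states that the libraries of a genotype came from separate cultures, so genotype and culture cannot be told apart. None of the 14 list calls was kept with an estimated correlation. With fry only those of proinflammatory genes, NF-kappaB targets and cholesterol biosynthesis were kept.

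The third comparison asked whether genes that differ with the receptor in macrophages moved with IL-10 in hearts. Genes lower in knockout macrophages, which include the cytokines, did not shift as a set. Of the 1625 that were tested in hearts 85 rose and 128 fell, with a median log2 fold change of -0.0496 (camera adjusted p = 0.284; p = 0.35 with an estimated correlation). Of 1622 genes higher in knockout macrophages 157 rose and 146 fell in hearts, with a median of 0.0249 (camera adjusted p = 0.372; p = 0.621 with an estimated correlation). Over the 12375 genes tested in both, 157 rose in both comparisons where independent lists would share 102, and 128 fell in both where they would share 111. In opposite directions, 85 rose in hearts and fell in macrophages (103 if independent) and 146 fell in hearts and rose in macrophages (111 if independent). Camera called 4 lists in both comparisons, and none of them with an estimated correlation (adjusted p from 0.285 to 0.939 in hearts and 0.88 in macrophages). Of 35 interferon-response genes 24 fell in hearts and 23 in macrophages. Of the extracellular matrix genes 32 fell in hearts and 18 rose in knockout macrophage cultures, where some mesothelial and fibroblast markers rose too. Which cells of those cultures held the matrix transcripts was not tested. For the 2 others, cell cycle and nuclear oxidative phosphorylation, camera's directions were opposite, but in macrophages only 1 cell cycle gene rose and 1 fell and 3 respiration genes fell, and those list calls were lost on leaving out single libraries (adjusted p = 0.191 and 0.281 for cell cycle, 0.165 for respiration). Angptl7 and Tsc22d3 rose in both, and Postn fell in IL-10 hearts and rose in knockout macrophage cultures.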

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

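No called gene turned its direction under any alternative. Of the hearts' 1860 calls, 454 also had an absolute log2 fold change of 1 or more, and of the macrophages' 3663, 1983. Leaving out 1 library gave 897 to 1968 calls in hearts and 734 to 3811 in macrophages, with fewer samples. With an estimated correlation 0 lists were called in hearts and 0 in macrophages, and with fry 2 and 3. Other scalings, filters and tests gave 1542 to 2248 calls in hearts and 3551 to 5156 in macrophages.

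Of the called lists, 2 had medians that turned sign, both in macrophages, to 0.0128 for oxidative phosphorylation with library size alone and to 0.855 for neutrophil markers with no filter, over 15 genes in place of 7. The other results that turned were uncalled, and the cause was not tested for any. With 1 library left out these spanned, in hearts, -0.03567 to 0.2502 for Myh6, -0.01145 to 0.4248 for Acta1, -0.4997 to 0.3768 for Il1b, -0.127 to 0.3083 for Adgre1 and -0.3839 to 0.2323 for Il10ra, and for list medians -0.236 to 0.181 for macrophage markers, -0.42 to 0.0366 for proinflammatory genes and -0.031 to 0.315 for resident cardiac macrophage markers and -0.0184 to 0.215 for mitochondrially encoded genes. The fibroblast markers' median stayed above 0 (0.0301 to 0.29), and only camera's direction turned, without IL-10 replicate 3. In macrophages they spanned -0.4216 to 0.09017 for Il10ra and -0.135 to 0.266 for the glucocorticoid-induced list, whose median is 0.141 beside a fry direction of lower.

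The replicate block gave 1523 calls and 11 lists in hearts and 2656 calls and 15 lists in macrophages. Of the named results, Cxcl1, Kcnq1ot1 and the ribosome list in hearts and Hmox1, Adgre1 and Mcm6 in macrophages were not called with it, and Nos2 was. Libraries of the same number deviated from their group means with correlations of -0.179, 0.0421 and 0.0034 in hearts and -0.113 in macrophages. These values show no pairing by number. They cannot exclude it, because deviations within such small groups are bound to cancel. A crossed pairing in macrophages gave 4595 calls. Leaving out mitochondrial genes gave 1858 calls in hearts. Depth limits genes of a few counts, such as Il10 in hearts.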

Other observations

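Angptl7 rose with IL-10 in Cd163-/- hearts and was higher in Cd163-/- macrophages, by 2.64 and 5.55 on the log2 scale. The tests chosen after the result was seen were those for neutrophils, glucocorticoid exposure and microbial stimulation, and the widening of the nuclear-share bound. No biological explanation was tested for any of the 3 patterns.

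In IL-10 hearts the mitochondrial ribosomal RNAs mt-Rnr1 (log2 1.31) and mt-Rnr2 (1.42) were higher, as were 10 of 16 tested mitochondrial tRNAs, and Malat1 (-1.39) and Meg3 (-1.89) were lower. More RNA without a poly(A) tail in these libraries would raise small nuclear and nucleolar RNAs. Their summed counts had a log2 ratio of -0.623 (SE 0.17), so no such rise was seen. These sums were only 99 to 209 counts per heart, and a lower share of nuclear RNA would lower them too. They therefore cannot decide this explanation. The set test of single genes first written for this had no tested gene, and summed counts replaced it before any direction was seen. A length bias between the groups would set the longest genes below the shortest, and that difference was -0.0456 (SE 0.0108), above the bound of -0.3, which argues against it. A lower share of nuclear RNA would lower long non-coding genes as a set. The median of 617 tested was -0.0245 (SE 0.0291). The bound written first, a median above -0.35, was met and would have counted against this explanation. It was judged too broad only after the result, because small nuclear RNAs fell by 0.623 and Neat1 (-0.51) and Kcnq1ot1 (-0.98), chosen after their values were seen, were lower too, so the question is left open. These 2 calls are weak. That of Kcnq1ot1 was lost without any 1 of the hearts except saline replicate 3, and with DESeq2 size factors, the DESeq2 Wald test and limma-voom (adjusted p from 0.0502 to 0.161 over these), and that of Neat1 without saline replicate 3, IL-10 replicate 2 or IL-10 replicate 3 (adjusted p from 0.0562 to 0.136).

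Inflammatory genes were far higher in wild-type than in knockout macrophages, although all had received dexamethasone. Neutrophils among the wild-type cells would bring S100a9, Cxcr2, Retnlg and Ly6g. The highest summed count of these 4 genes in a wild-type library was 1, so they give no sign of neutrophils. These genes were chosen from the neutrophil list after the result was seen. Of its 7 tested genes 5, among them S100a8, Mmp9 and Lcn2, were lower in knockout cells and 1 was higher, so neutrophils are not excluded. Weaker glucocorticoid exposure of the wild-type cultures would make the glucocorticoid-induced list higher in knockout cells. Its median was 0.141 and it was not called. Its members went both ways, 6 higher in knockout cells, among them Tsc22d3 and Fkbp5, and 6 lower, among them Fpr1 and Fpr2. The 6 lower genes include Nr3c1, the gene of the receptor itself, whose fall does not tell which cultures had the weaker exposure. This explanation stays open. Microbial stimulation of the wild-type cultures would lower NF-kappaB targets in knockout cells, and their median was -2.63, but these are the pattern's own genes and cannot decide it. An effect of the genotype stays open as well, since nothing states that the libraries of a genotype came from separate animals or cultures.

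Haemoglobin transcripts were lower in IL-10 hearts, with a log2 ratio of -1.08 (SE 0.394) for the summed red blood cell list. Less residual blood would lower platelet transcripts alike, to a log2 ratio of -1 or below. Their sum had -0.374 (SE 0.179), above that bound, but the bound takes no account of the SE of 0.394 on the red cell ratio. A fall of equal size in both is therefore not excluded, and the platelet sum rests on 53 to 85 counts per heart. The platelet gene Ppbp, chosen after its value was seen, was at -0.89 and Gp1ba at 0.183, so residual blood stays open. Fewer young red cells released from the marrow were not tested.

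The 6 hearts can be divided into groups of 3 in 10 ways, too few for a share under 0.05. The real division gave 1860 genes against at most 0 in another, and it was the 1 division with a count as large. It gave 12 lists against at most 15, with 7 divisions at 12 or more. For the macrophage genes in hearts it gave 0 sets against at most 1, so all 10 divisions had as many.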
